A study of Homo sapiens with 3 samples.

How the data were processed

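Total RNA of A375 melanoma cells was measured on Illumina expression arrays in 3 states, adherent, suspended and reattached for 1 day, with 1 array each. Per the labels' protocols, the cells grew in medium with 10% serum, RNA was extracted with Trizol and biotinylated cRNA was made with an Ambion kit. The deposited scanner table holds, per the file headers, 1 signal intensity and 1 detection p-value per probe and array. The intensity values are linear, positive and not normalized between arrays, and the detection p-value runs in steps of 1 in 770. Scanner software and any earlier background step are not given in the sources used here. The authors' second table holds intensity values with nearly the same distribution in all 3 columns (medians 58.1 on each array), on a linear scale, uncentred, with background left in. Within each array its probes have the order of the scanner table (Spearman correlation 1). How that shared distribution was made is not given in the sources used here, and the table served as an alternative only.

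From the scanner table, background was corrected and arrays were normalized with neqc of limma 3.58.1 (R 4.3.3), which infers the negative controls from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. Probes were named from the platform annotation: of 47323 probes, 30113 had 1 gene symbol, 8 had several genes and were left out, and 17202 were unnamed here. Entrez identifiers of 30074 probes were found in the GRCh38.p14 gene table, and no symbol changed. A probe counted as detected at a detection p-value under 0.01. Each gene was represented by its detected probe with the highest mean log2 level, and a gene entered a comparison when it was detected on at least 1 of the 2 arrays. Where it was not detected, its value was raised to the lowest level of a detected probe on that array if it lay under it, so that such differences are bounds written as at least so many fold.

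Since each state had 1 array, no test of a difference between states was run and no p-value or spread over replicates is given. The counts at 2-fold, the share of genes within 1.5-fold of the adherent level, the correlation across genes and the medians of 43 gene lists (782 entries, 608 found among detected genes) were fixed before the data were examined. The lists cover metabolism, stress responses, cell cycle, apoptosis, adhesion and cytoskeleton, matrix, melanoma states, signalling, markers of other cell types and reference genes. A list's median was set against 10000 random lists of equal size, drawn from 20 classes of mean expression, as a description only. The rule for naming genes was the 10 highest and 10 lowest differences among genes detected on both arrays, the 3 brightest genes detected on 1 of the arrays in each direction, the 4 leading members of a list that stood apart and the 2 leading members of any other list, of which some are named. The rankings of 10 and of 3 left out symbols that begin with LOC or with HS and a dot, or that contain KIAA, FLJ, MGC or orf. Members that ran against their list, ITGB7, genes that crossed the adherent level, and a few further members were named after their values were seen.

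Chance was described with 100 simulated sets of 3 unchanged arrays, whose noise was drawn from the reattached minus adherent differences of genes of like intensity, divided by the square root of 2. This noise holds any real difference between those arrays, but it comes from a single pair. It does not measure the noise of the suspended array or the variation between cultures, so it does not bound chance for suspended against adherent cells, and it is circular for the comparison of those arrays, for which no simulated count of genes at 2-fold is given. The simulated shares, shared counts and correlation also use that comparison and serve as a reference only. The full-return and mixture simulations were added after the results were seen. The random sign of the noise was added after a first version had been seen, which gave simulated shares back near the adherent level of 25.1% for higher and 79.2% for lower genes. The procedure was tested on simulated data for suspended against adherent with 11179 genes compared. It called 50 of 50 genes raised 4-fold, 41 of 49 lowered 4-fold, 50 of 50 raised 3-fold and 43 of 50 lowered 3-fold, and 0 of 10980 unchanged genes, and 1 of 100 random lists stood apart. The simulated differences of unchanged genes had an SD of 0.158, less than the 0.298, 0.225 and 0.219 of the arrays, so the 0 is not their rate of false calls, and the simulated unchanged arrays, at 5.57 higher and 5.43 lower genes, are the closer reference. Signal over background limits precision, and so does the number of arrays. Detected probes made up 37.5%, 36.9% and 35.6% of probes on the adherent, suspended and reattached array.

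Alternatives were median scaling (over 16154 probes detected on all 3 arrays, a set chosen after the tables were seen), cyclic loess, no background correction, normexp without controls with offset 50, neqc with offset 50, the authors' deposited normalized values, 3 other detection filters, the mean over probes, thresholds of 1.5-fold and 3-fold and a tolerance of 1.2-fold. Counting the SPANX genes as 1 gene and leaving out small structural RNA genes were chosen after seeing the data. No scaling moved the median of all genes by more than 0.1. Coordinates are left out because the array's genome build is not given in the sources used here.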

Results

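The A375 line is an established human melanoma cell line that grows attached to the dish. Expression was measured on 3 Illumina arrays of total RNA, 1 from adherent cells, 1 from cells kept in suspension and 1 from suspended cells given 1 day to attach again. How long the cells were kept in suspension, and from how many cultures each RNA came, is not given in the sources used here. Each array carried 47323 probes. Detected probes numbered 17761 on the adherent, 17466 on the suspended and 16826 on the reattached array, with median signals of 233, 262 and 247, 4.66, 5.01 and 4.95 times the median of undetected probes. In all, 11062 named genes were detected on at least 1 array and 9984 on all 3. With 1 array per state, no difference given here has a replicate check and no test of a difference between states was made, and intervals over genes do not stand in for replicates. Values are differences between single arrays on the normalized log2 scale, on which the offset of 16 makes differences of dim genes smaller than they are.

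The comparison of suspended with adherent cells sets cells without anchorage against attached ones. The carboxypeptidase gene CPA4 was 10.5-fold lower in suspension, the secreted trefoil peptide TFF2 6.40-fold and the membrane protein TM4SF18 5.93-fold. In the other direction, the cornified envelope precursor SPRR2D was 4.49-fold higher, the prostaglandin synthase PTGS2 3.94-fold and the chemokine CXCL8 2.87-fold. Targets of the mechanosensitive regulators YAP and TAZ, actin and SRF genes and focal adhesion genes were lower as groups. Targets of NF-kB, genes of the unfolded protein response and genes of the pigment cell program were higher as groups.

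At 2-fold or more, 55 genes were higher and 72 lower in suspension, 1.16% of the 10991 genes compared. In 100 simulated sets of unchanged arrays, with noise taken from the reattached and adherent pair alone, the same counts were 5.57 higher (range 1 to 11) and 5.43 lower (range 0 to 11) on average. Among genes detected on both arrays, the log2 differences had an SD of 0.298 and the log2 levels a correlation of 0.988 across genes. Of 31 genes at 2-fold with a second detected probe, the second probe had the same sign in 27 and reached 2-fold in 19. With background left in, the counts were 32 and 37, and with the authors' deposited normalized values 30 and 37.

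The 10 ranked genes that were lowest in suspension relative to adherence also included ARHGDIB (-2.28), FGFBP1 (-2.24), SPANXA1 (-2.08), ADGRF1 (-1.97), EFEMP1 (-1.95), CALB2 (-1.94) and SPANXC (-1.92), given as log2 differences. C19orf33 (-2.02), left out of the rankings by its symbol, was also lower. FGFBP1 carries fibroblast growth factors out of the matrix, EFEMP1 is a fibulin of the extracellular matrix and CALB2 is the calcium-binding protein calretinin. SPANXA1 and SPANXC belong to a cancer-testis family of near-identical genes whose probes may not tell the members apart, so their values are uncertain as values of single genes. The second probe of CALB2 differed by -0.09 and the other probes of ADGRF1 by -0.80 and -0.08, far less than the probes named above, and that of TM4SF18 by -1.91. Detected in adherent but not in suspended cells were the kinase gene ALPK2, at least 5.90-fold lower, the membrane trafficking gene MAL2, at least 3.16-fold lower, and the sodium channel subunit SCNN1A, at least 2.55-fold lower.

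Higher in suspension by the most, after SPRR2D and PTGS2, were TAGLN3 (1.85), LRRK2 (1.79), SLC25A24 (1.67), MIR302C (1.58), ID3 (1.57) and TESC (1.53), followed by CXCL8 and the receptor gene MRGPRX4 (1.52). ID3 is an inhibitor of helix-loop-helix transcription factors, LRRK2 a large kinase, SLC25A24 a mitochondrial carrier and TESC a calcium-binding protein. A second PTGS2 probe gave 0.59, a second TAGLN3 probe 1.19 and a second CXCL8 probe 1.52, whereas the second SLC25A24 probe gave -0.60, the opposite sign. Detected in suspended but not in adherent cells were the glycolipid galactosyltransferase A4GALT, at least 2.93-fold higher, the collagen gene COL9A2, at least 2.83-fold higher, and the homeobox gene LHX8, at least 2.40-fold higher.

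**Figure D1:**
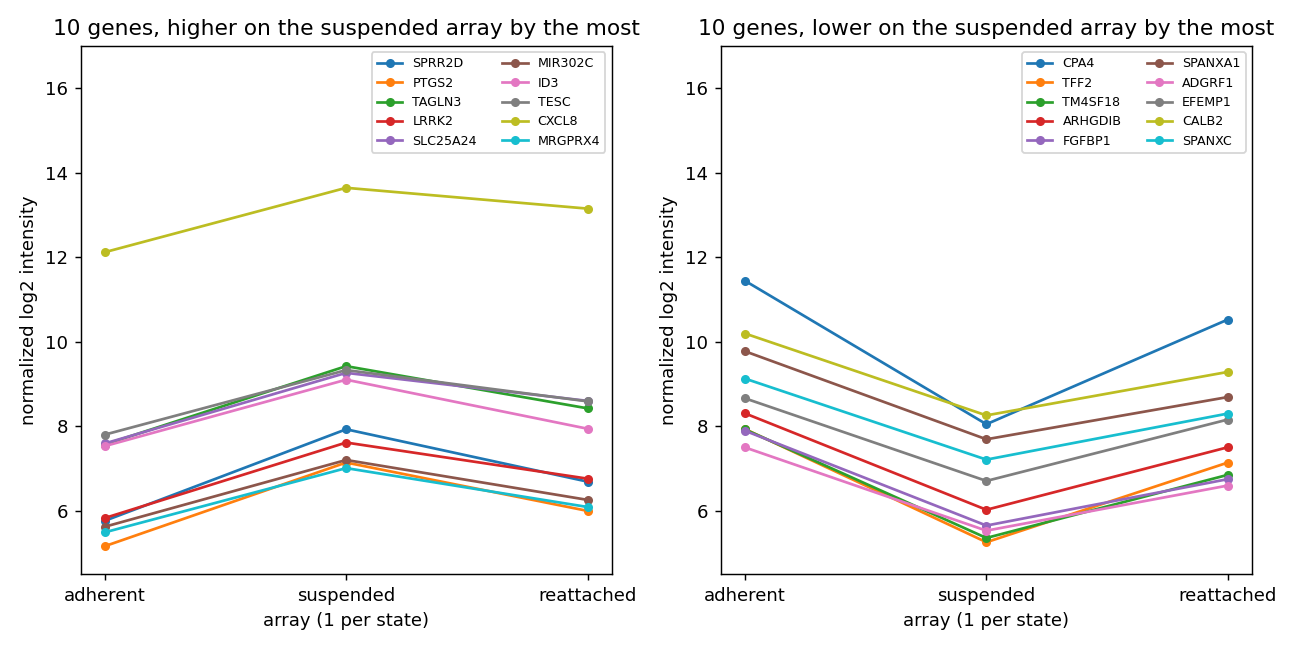
Normalized log2 intensity of the 10 genes with the largest positive (left) and the 10 with the largest negative (right) difference between the suspended and adherent arrays, among genes detected on both and not left out by symbol, with 1 point per array and lines joining the points of a gene. Each line on the left peaks and each on the right dips at the suspended array, CPA4 by -3.39, and the reattached point lies between the other 2.

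Of 42 gene lists with at least 3 measured members, 16 stood apart between suspended and adherent cells, 10 higher and 6 lower, where chance would give 0.84 each way. A list stood apart when its median lay under percentile 2 or over percentile 98 of 10000 random lists of the same size matched on mean expression. These percentiles describe the arrays only, since the members of a list may vary together. Some genes also belong to more than 1 list, as ICAM1 and VCL do, so the 16 lists are not separate results. NF-kB targets and inflammatory cytokines had the largest median of the 42, 0.44 (percentile 100), with 17 of 21 members above 0. After PTGS2 and CXCL8, that list was led by the adhesion receptor ICAM1 (0.84) and the cytokine IL24 (0.74), and the neutrophil chemokine CXCL2, not detected in adherent cells, was at least 1.92-fold higher, while the monocyte chemokine CCL2 (-1.10) and IL1B (-0.54) were lower. All 16 measured genes of the unfolded protein response lay above 0, with a median of 0.27 (percentile 100). They were led by EDEM1 (0.64), which disposes of misfolded glycoproteins, the disulfide isomerase PDIA6 (0.56), the stress sensor ATF6 (0.52) and the co-chaperone DNAJC3 (0.51). In contrast, genes of the ATF4 and amino acid response were lower, with a median of -0.20 (percentile 0.05), 13 of 18 below 0. STC2 (-0.75), ATF3 (-0.69) and the paired amino acid transporter chains SLC7A5 (-0.53) and SLC3A2 (-0.51) led it, and VLDLR (0.95) and the asparagine synthetase ASNS (0.63) went the other way.

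By their medians, YAP and TAZ targets, actin and SRF genes and focal adhesion components were lower in suspension. YAP and TAZ targets had a median of -0.26 (percentile 0.01), 14 of 19 below 0, led by the matricellular gene CCN1 (-1.03), the LIM protein AJUBA (-0.64), CRIM1 (-0.62) and the tissue factor gene F3 (-0.60). ANKRD1, not detected in suspension, was at least 1.88-fold lower. For actin cytoskeleton genes and SRF targets the median was -0.24 (percentile 0.01), 10 of 13 below 0, and calponin CNN2 (-0.79), vinculin VCL (-0.37), TGFB1I1 (-0.37) and ACTA2 (-0.33) led it. Focal adhesion components had a median of -0.18 (percentile 0.04), 16 of 20 below 0, with the caveolins CAV1 (-1.24) and CAV2 (-0.86) ahead of VASP (-0.49) and parvin PARVA (-0.48), although the other CAV2 probes gave -0.96 and -0.14.

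Integrins, the receptors for matrix, ran the other way, with a median of 0.27 (percentile 99.96) and 9 of 13 above 0. ITGA1 (1.09), ITGB8 (0.97), ITGB3 (0.63) and the fibronectin receptor chain ITGA5 (0.41) led them, while ITGB4, the laminin receptor chain of hemidesmosomes, was not detected in suspension and at least 2.35-fold lower, with a second probe at -0.69. ITGB7, an integrin gene outside the list, was also lower (-1.05). Extracellular matrix genes had a median of 0.23 (percentile 99.99) but spread widely. LAMA4 (1.41), COL4A1 (0.94), HAPLN1 (0.90) and LAMB2 (0.85) were higher, and the small proteoglycan BGN (-1.91), the fibrillar collagen COL5A1 (-1.07) and the laminin chain LAMA5 (-0.92) were lower. Matrix proteases and inhibitors had a median of 0.26 (percentile 99.99), with the metalloprotease inhibitor TIMP1 (1.06), ADAMTS1 (0.98), CTSK (0.62) and the urokinase receptor PLAUR (0.60) in front. Cell-cell adhesion genes had a median of 0.16 (percentile 98.7), led by ICAM1 (0.84), CTNNA1 (0.40), DSG2 (0.34) and MCAM (0.34), whereas the neural adhesion molecule L1CAM was lower (-1.71).

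Pigment cell genes and MITF targets had a median of 0.42 (percentile 99.99), 6 of 8 above 0, with GPNMB (0.64), RAB38 (0.47), the melanocortin receptor MC1R (0.46) and the lineage factor SOX10 (0.44) in front. Only 8 of the 20 listed genes were measured. Autophagy and lysosome genes stood at 0.15 (percentile 99.51; WIPI1 0.53, CTSA 0.36, LAMP2 0.34), FOXO targets at 0.18 (percentile 99.2; BCL6 0.59, TRAF4 0.57, IRS2 0.48) and hypoxia-inducible genes at 0.13 (percentile 98.2; PFKFB4 0.71, P4HA2 0.64, MXI1 0.47). Genes of G2/M and mitosis had a median of -0.10 (percentile 1.18), 21 of 27 below 0, led by the mitotic kinases PLK1 (-0.36) and AURKB (-0.29), CCNB1 (-0.28) and KIF2C (-0.27). Replication-dependent histones had a median of -0.34 (percentile 0.03) over 7 members, with H2AC18 (-0.75), H2BC5 (-0.67), H2BC12 (-0.59) and H1-2 (-0.34) lowest. These histone genes resemble each other in sequence, which leaves single values uncertain. The hypoxia list no longer stood apart under median scaling or cyclic loess, and the cell-cell adhesion list under the looser filters or the mean over probes. Without a detection filter the hypoxia, matrix and FOXO lists did not stand apart and the pigment cell median was 0.13, the autophagy list did not stand apart with the mean over probes, which gave a protease median of 0.15, and the NF-kB median was 0.29 under normexp with offset 50.

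**Figure D2:**
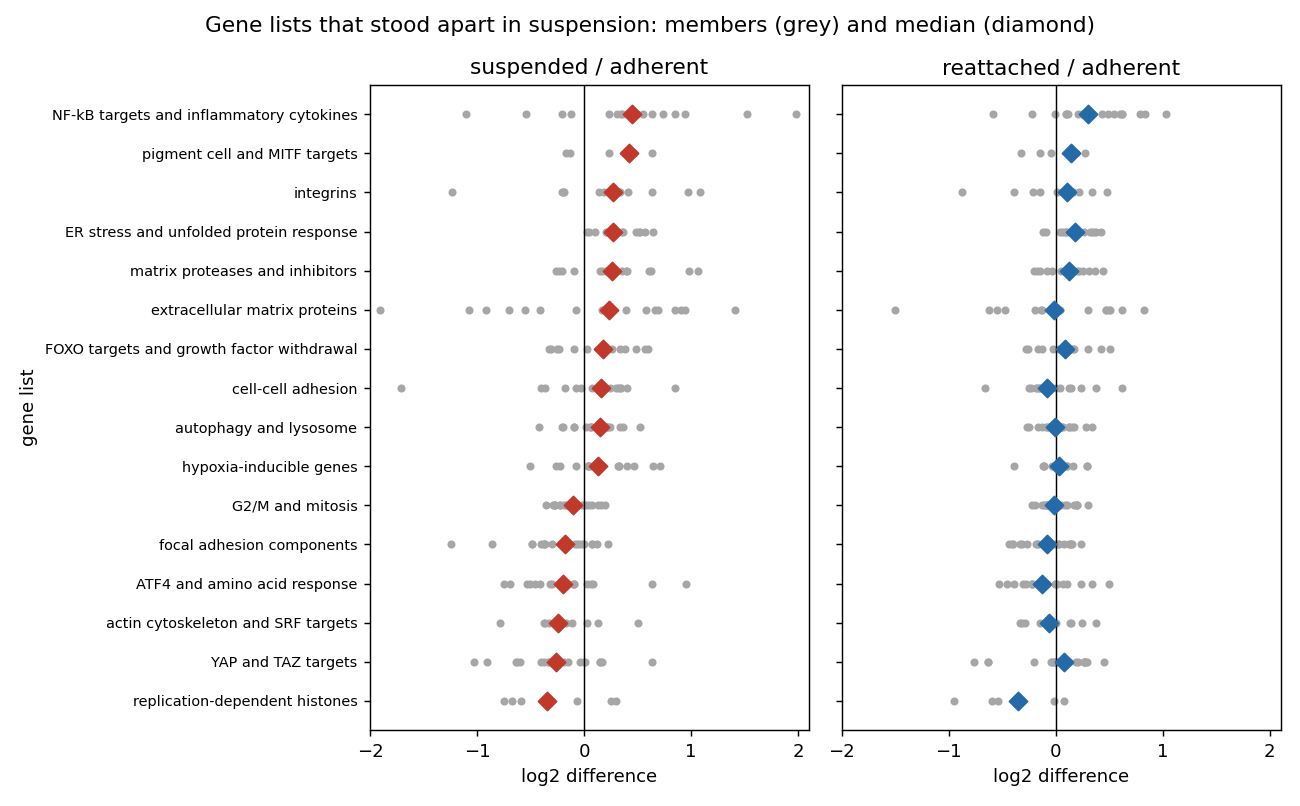
Log2 differences of suspended over adherent (left) and reattached over adherent (right) for the 16 gene lists that stood apart in suspension, with grey points for members and a diamond for the list median. The NF-kB median was 0.44 in suspended and 0.30 in reattached cells against adherent cells, and the YAP and TAZ median -0.26 and 0.08.

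Many other lists had medians inside the random range between suspended and adherent cells, a range that is wide for lists with few members such as the 4 metallothioneins. Medians were 0.05 for cholesterol synthesis (LSS -0.50, HSD17B7 0.46), -0.07 for fatty acid synthesis (ELOVL6 -0.36, SREBF1 -0.33), 0.00 for glycolysis (SLC2A1 -0.55, PFKP -0.19) and -0.02 for oxidative phosphorylation (NDUFS1 -0.30, ATP5PB -0.28). Stress lists stood at 0.00 for heat shock (HSPA6 0.91), 0.00 for NRF2 targets (GCLC -0.28, with a second probe at 0.95), -0.09 for p53 targets (RRM2B -0.27, MDM2 -0.26) and -0.19 for metallothioneins (MT1E -0.70, MT1G -0.37). G1/S and DNA replication genes had a median of 0.01 (FEN1 0.21), cyclin-dependent kinase inhibitors -0.09 (CDKN1C -0.53), cytosolic ribosomal proteins -0.03 (RPS19 -0.23), ribosome biogenesis and MYC targets 0.03 (ODC1 0.27) and serine and one-carbon metabolism 0.04 (GLDC 0.42). Apoptosis genes had medians of -0.03 for BH3 and BAX family members (BID -0.38, with other probes at -0.26 and 0.19, PMAIP1 -0.31) and 0.06 for inhibitors of apoptosis (MCL1 0.53). BAX itself stood at -0.03 with the probe used, but another BAX probe gave -1.30.

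Signalling and melanoma state lists also stayed inside the random range. The median was 0.05 for ERK pathway output (EGR1 0.95, PHLDA1 0.53), -0.01 for immediate early genes (ATF3 -0.69, KLF4 -0.57), -0.06 for type I interferon genes (XAF1 -0.56, OAS3 -0.53) and 0.12 for TGF-beta targets (ID3 1.57, PMEPA1 2.30-fold higher). Immediate early genes were split, since EGR3 (1.32) and NR4A2 (1.00) were among the higher ones. EMT transcription factors had a median of 0.01 (TWIST1 0.54, ZEB2 0.43), genes of the invasive dedifferentiated state -0.06 (THBS1 -0.55, EGFR -0.38) and neural crest and stemness markers -0.09 (KLF4 -0.57, MSX1 -0.54). Reference genes had a median of 0.02, with GUSB at 0.40 and YWHAZ at -0.34 farthest from 0. Markers of other cell types had medians of -0.01 for fibroblasts (5 of 12 measured), -0.06 for keratinocytes and epithelia (5 of 14) and -0.03 for leukocytes (4 of 14), all inside the random range. The keratinocyte and epithelial list had 2 members above 0 and 3 below, with a mean of -0.29, and its members KRT14 and KRT8 were not detected in suspension. Only 2 endothelial markers were measured, ENG (0.25) and PECAM1 (0.02, a level near the detection limit and not detected in suspension), too few for a percentile.

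The comparison of reattached with suspended cells sets cells 1 day after attachment against cells without anchorage. CPA4 was 5.57-fold, TFF2 3.69-fold, TM4SF18 2.82-fold and ARHGDIB 2.79-fold higher in reattached than in suspended cells. The small nuclear RNAs of the spliceosome RNU4-2 and RNU4-1 were 2.93-fold and 2.70-fold lower, and SPRR2D, ID3 and PTGS2 were 2.36-fold, 2.24-fold and 2.21-fold lower. YAP and TAZ targets, actin genes and focal adhesion genes were higher as groups, and matrix genes, integrins, pigment cell genes and the unfolded protein response lower.

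At 2-fold or more, 22 genes were higher and 12 lower in reattached than in suspended cells, of 10715 compared. Simulated unchanged arrays gave 5.25 (range 1 to 13) and 5.37 (range 1 to 11), so that the 12 lower genes lay just above the simulated range. Small structural RNA genes made up 5 of those 12, with RNU4-1 and RNU4-2 counted apart, and without all such genes the counts were 22 and 7. Of 7 genes at 2-fold with a second probe, it had the same sign in 6 and reached 2-fold in 2. With background left in, 11 genes were higher and 8 lower, and with the authors' deposited normalized values 9 were higher and 7 lower. Further genes that were higher were EFEMP1 (1.45), CCN1 (1.30), SPANXA2 (1.29), TGM2 (1.21), KRT80 (1.16) and EVA1A (1.13), of which TGM2 is a transglutaminase that cross-links matrix proteins and KRT80 a keratin. Other probes gave 0.21 and 0.39 for TGM2, 0.82 for TM4SF18 and 0.97 and 1.03 for EVA1A. ALPK2, at least 2.43-fold, the actin-binding gene NEXN, at least 2.20-fold, and ARHGAP30, at least 1.70-fold higher, were detected after reattachment and not in suspension. Further genes that were lower were HINT3 (-1.33), CD55 (-1.28), RN7SK (-1.26), COL9A2 (-1.15) and RMRP (-1.14); CD55 protects cells from complement, and RN7SK and RMRP are structural RNAs. A second probe gave -0.06 for HINT3 and -0.43 for PTGS2. ELMOD3, NTS and PDE3A were detected in suspended cells and not after reattachment, at least 1.77-fold, 1.76-fold and 1.75-fold lower.

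Of the 42 lists, 5 stood apart higher and 8 lower between reattached and suspended cells. YAP and TAZ targets had a median of 0.29 (percentile 100), 15 of 18 above 0, led by CCN1 (1.30), AJUBA (0.63), CRIM1 (0.59) and GADD45B (0.53). Actin and SRF genes had a median of 0.17 (percentile 99.9), led by CNN2 (0.50) and the tropomyosins TPM1 (0.41) and TPM4 (0.39, with a second probe at -0.01). Focal adhesion genes had a median of 0.11 (percentile 99.1; CAV1 0.83, CAV2 0.42 with other probes at -0.13 and 0.55), cholesterol synthesis 0.12 (percentile 98.2; LSS 0.40, MVK 0.38) and G1/S and DNA replication 0.10 (percentile 98.8; TK1 0.25, MCM6 0.25). On the lower side were TGF-beta targets at -0.28 (percentile 0.01; ID3 -1.16, PMEPA1 -0.85, ID1 -0.73), pigment cell genes at -0.27 (percentile 0.26; GPNMB -0.46, MC1R -0.27) and matrix genes at -0.19 (percentile 0; SPARC -0.67, LAMA4 -0.59). Integrins stood at -0.15 (percentile 0.29; ITGA1 -0.97, ITGB8 -0.64), matrix proteases at -0.15 (percentile 0.24; TIMP1 -0.70, ADAMTS1 -0.67) and the unfolded protein response at -0.14 (percentile 0.13; CRELD2 -0.37, HSP90B1 -0.33). Autophagy and lysosome genes had a median of -0.14 (percentile 0.16; NEU1 -0.32) and NF-kB targets -0.12 (percentile 0.77; PTGS2 -1.14, TNFAIP3 -0.57), although CCL2 was higher (1.09). The G1/S list stood apart in 4 of 10 alternative processings, the cholesterol and TGF-beta lists in 8, and the actin list in 9, all but the mean over probes. Without a detection filter the matrix, protease, NF-kB and TGF-beta lists did not stand apart and the pigment cell median was -0.17, and the YAP and TAZ median was 0.13 under normexp with offset 50 and 0.16 with background left in.

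The comparison of reattached with adherent cells sets cells attached again against cells that stayed attached. The chemokine CXCL8 was 2.04-fold and SLC25A24 2.01-fold higher in reattached than in adherent cells, while BGN was 2.83-fold, FGFBP1 2.21-fold and SERINC2 2.18-fold lower. The largest negative difference was that of TELO2, a factor that stabilizes large kinases of the DNA damage response, at 3.39-fold. NF-kB targets and the unfolded protein response were higher as groups, whereas YAP and TAZ targets had a median of 0.08, inside the random range.

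In total, 4 genes were at least 2-fold higher and 11 lower in reattached than in adherent cells, of 10821 compared. The higher ones were CXCL8, SLC25A24, the small nucleolar RNA SNORD22 (1.03) and FDCSP, at least 2.25-fold. Of the 4, CXCL8 and SLC25A24 were also at least 2-fold higher in suspension, and the second SLC25A24 probe again went the other way (-0.37). The lower ones also included ALPK2 (-1.28), SPANXA1 (-1.08), MANCR (-1.08), TM4SF18 (-1.07), SCNN1A (-1.05) and SERPINB7 (-1.01) and MAL2, at least 2.91-fold, and 10 of the 11 were also at least 2-fold lower in suspension, the exception being the noncoding gene MANCR. A second probe gave -0.19 for SERPINB7 and -0.82 for SPANXA1, and those of PTPN22 gave -0.12 and 0.54. Both comparisons use the same adherent array, whose noise alone puts genes in both. Simulated unchanged arrays shared 1.24 higher (at most 6) and 1.11 lower genes (at most 3), and arrays simulated with the observed suspension differences and a full return 1.32 (at most 5) and 1.36 (at most 5). The 10 shared lower genes lay above both ranges and the 2 shared higher genes inside them. Both simulations spread the noise evenly over the arrays. A deviation of the adherent array alone, which would put a gene in both comparisons, is therefore not covered and stays open. Just under 2-fold higher were PTPN22 (0.99), CYP4B1 (0.97), PXYLP1 (0.94), LRRK2 (0.93), SPRR2D (0.93), DAAM2 (0.89) and CDC42EP5 (0.86), and the bounds included ADGRA2, at least 1.95-fold higher, LHX8, at least 1.76-fold higher, and KCNJ2 and H4C12, at least 1.86-fold and 1.78-fold lower. With background left in, the counts were 1 and 5, with the authors' deposited normalized values 1 and 4, and with cyclic loess 2 were higher. Under a detection p-value of 0.05 the lower genes numbered 18 and without a filter 20.

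Of the 42 lists, 4 stood apart higher and 4 lower between reattached and adherent cells. NF-kB targets had a median of 0.30 (percentile 100), 17 of 20 above 0, led by CXCL8 (1.03), PTGS2 (0.84), NFKB2 (0.78) and ICAM1 (0.62). The unfolded protein response had a median of 0.18 (percentile 99.98), 14 of 16 above 0, led by PDIA6 (0.42), PDIA4 (0.38) and the chaperone HSPA5 (0.36). Heat shock genes stood at 0.12 (percentile 99.4; HSPA6 0.54, HSPA1B 0.34) and cholesterol synthesis at 0.12 (percentile 98.4; HSD17B7 0.33, EBP 0.33), the latter in only 2 of 10 alternative processings. Replication-dependent histones had a median of -0.35 (percentile 0.04; H2BC5 -0.95, H2BC12 -0.59), ATF4 and amino acid response genes -0.13 (percentile 0.16; ATF3 -0.53, PSPH -0.45), focal adhesion genes -0.09 (percentile 1.64; CAV2 -0.44, CAV1 -0.41) and p53 targets -0.09 (percentile 1.91; TP53INP1 -0.62), the p53 list in 5 of 10 alternative processings. The heat shock list did not stand apart under median scaling, the focal adhesion median was -0.14 with the mean over probes, and the p53 median was -0.15 with genes detected on both arrays.

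Most genes that differed in suspension had a reattached level between those of adherent and suspended cells, a place that selection on the suspended minus adherent difference favors by itself. Of the 55 genes higher in suspension, 53 had a reattached level between the other 2, and RNU4-1 and RNU4-2 lay below the adherent level. Of the 72 lower genes, 69 lay between, CCN1 and NEXN were above the adherent level and TELO2 was lower still. The 69 include MAL2 and KCNJ2, detected neither in suspended nor in reattached cells. Their place between comes only from the lowest detected levels set for those arrays, 5.18 and 5.29. The shares between were 96.4% of the higher and 95.8% of the lower genes, against 76.7% and 79.6% in simulated unchanged arrays. Within 1.5-fold of the adherent level were 26 of the 55 (47.3%, exact 95% binomial interval 33.7 to 61.2) and 27 of the 72 (37.5%, interval 26.4 to 49.7), where the interval covers the sampling of genes only. Simulated unchanged arrays, in which genes pass 2-fold by noise alone, gave 51.3% and 52.9%. Among the genes higher in suspension, the median share of the log2 difference left was 46.2%, and among the lower genes 44.5%. Simulated unchanged arrays gave 51.0% and 47.9%, but their equal noise on each array sets such a share in advance. They also gave far fewer genes at 2-fold, 5.57 higher and 5.43 lower on average. They therefore cannot decide how much of either share is a partial return, and neither share by itself shows one. Across 10750 genes, which are not independent replicates, the suspension and reattachment differences from the adherent array correlated with r = 0.68, against 0.500 (range 0.475 to 0.521) in simulated unchanged arrays that share the adherent array in the same way. The covariance was 0.0453 against 0.0244 simulated, a difference of 0.0210. The adherent array enters both differences, and as a single array it cannot be split into separate controls. Of the genes higher in suspension, 65.6% lay within 1.5-fold with background left in, and 14.5% within 1.2-fold.

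**Figure D3:**
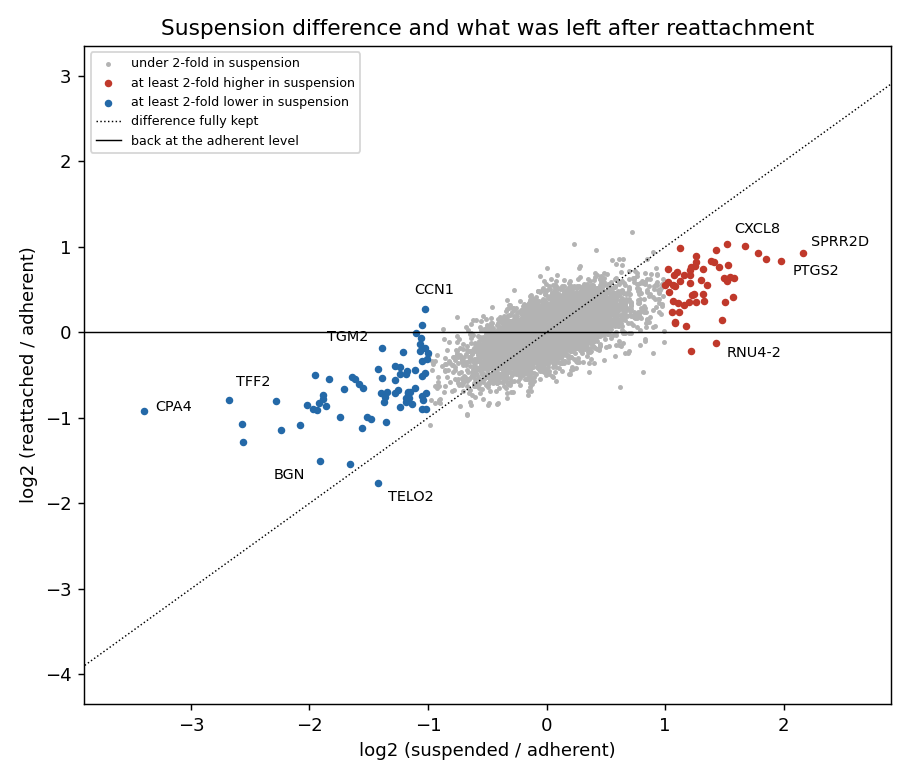
Log2 difference of each of 10750 genes between suspended and adherent (x axis) and reattached and adherent cells (y axis), with 1 point per gene and red and blue for the 55 genes at least 2-fold higher and 72 lower in suspension. Most colored points lie between the dotted line of a fully kept difference and the solid line of the adherent level, with CCN1 at 0.28 above it and TELO2 at -1.76 beyond the dotted line.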

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

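Both values in this part come from probes without a gene name, which the comparisons between states do not use, and no test in this part was planned for them. Of 3933 such probes detected in suspended or adherent cells, 5 were at least 2-fold higher and 18 at least 2-fold lower on the suspended array. Of those with the largest differences, the brightest were 1 probe with log2 levels of 10.66 in adherent, 8.86 in suspended and 9.95 in reattached cells, and 1 with 9.11, 10.60 and 9.82. Their reattached levels lay between the other 2. Between reattached and suspended cells 4 were higher and 2 lower, and between reattached and adherent cells 0 were higher and 4 lower. These probes stand here because they carry signal but entered no gene comparison. The genes they read are not known here, and no explanation is offered.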

How the results depend on the processing

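The size thresholds, the tolerance and the first 10 alternatives were planned, except that the probe set of median scaling was chosen after the tables were seen. The last 2 alternatives were chosen after seeing the data. Of 680 values of named genes at 2-fold or more under the 10 alternative processings, 680 kept their direction, 575 still reached 2-fold and 105 did not. Of 370 values of lists that stood apart, 370 kept their direction and 333 still stood apart, 37 did not. Of 118 alternative values of the counts, shares and correlation, 71 counted as the same, which for a count means within 1.5 times the main count, for a share inside its exact 95% interval, and for the correlation inside its bootstrap 95% interval over genes, 0.66 to 0.69. The 9 values under median scaling, the 9 with genes detected on both arrays and the 9 with the mean over probes did so. Signal over background limits dim genes, whose differences shrink with background left in or a larger offset. No paired analysis was possible because each state had 1 array. The cause was not tested for any value that moved except where the construction shows it (background or offset added to each value, or another threshold).

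Counts are given as higher and lower genes in suspended against adherent, reattached against suspended and reattached against adherent cells. Without background correction they were 32 and 37, 11 and 8, and 1 and 5, and the share of genes higher in suspension that returned was 65.6%. Normexp without controls, which was run with offset 50 so that both choices differ, gave 28 and 32, 8 and 7, 1 and 2, and a share of 75%, offset 50 alone gave 32 and 38, 11 and 8, 1 and 5, and 65.6%, and the authors' deposited normalized values gave 30 and 37, 9 and 7, 1 and 4, and 63.3%. Cyclic loess gave 2 higher and 12 lower genes in reattached against adherent cells, a split of 14.3% higher instead of 26.7%, and under normexp with offset 50, 53.3% instead of 64.7% of the genes at 2-fold between reattached and suspended cells were higher. A detection p-value under 0.05 gave 18 lower genes in reattached against adherent cells and no filter 20, with a correlation of 0.62 over 20046 genes. At 1.5-fold the counts were 298 and 245, 88 and 117, 94 and 119, and at 3-fold 5 and 22, 2 and 0, 0 and 1. At 3-fold, 0% of the 5 higher and 18.2% of the 22 lower genes returned, and within 1.2-fold 14.5% and 12.5% did. Without small structural RNA genes, 7 genes were lower in reattached than in suspended cells.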

Other observations

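All tests in this part were chosen after the values had been seen. Among gene families that were not fixed lists themselves, the HLA genes, which present antigens, were mostly higher in suspension, 15 of 17 above 0 with a median of 0.27, led by HLA-B (0.85), HLA-DQB1 (0.47) and HLA-F (0.47). After reattachment their median against adherent cells was 0.15. Near-identical sequences leave single HLA values uncertain. Keratin genes, which build intermediate filaments of epithelia, were lower in suspension, 7 of 8 below 0 with a median of -0.66, led by KRT80 (-1.89) and KRT9 (-1.21), with KRT14 and KRT8 not detected in suspension and at least 1.98-fold and 1.92-fold lower. The keratin median was 0.31 in reattached against suspended cells. KRT14 and KRT8 also belong to the fixed list of keratinocyte and epithelial markers, whose median in suspension was -0.06, inside the random range. Over the 7 normalizations tried, the keratin medians ran from -0.71 to -0.32 in suspended against adherent and from 0.14 to 0.39 in reattached against suspended cells, and the HLA median in suspension from 0.25 to 0.27. The cancer-testis genes of the MAGE, GAGE and PAGE families had a median of -0.07 in suspension over 32 genes, unlike the SPANX genes.

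Small structural RNA genes, which serve splicing, ribosome assembly and protein export, were higher on the suspended array, with 90 of 116 above 0 and a median of 0.22 (bootstrap interval over genes 0.15 to 0.28), the highest of 7 normalizations, of which the lowest gave 0.12. RNU4-2 (1.43), RNY4 (1.32), RNU4-1 (1.22), SNORA73A (0.99) and RNVU1-18 (0.99) led them. A group taken to have their own promoters was set by symbol (RNU, RNVU, RN7SK, RN7SL, RMRP, RPPH1, RNY, SNORD3A, SNORD3C and SNORD3D). The remaining SNORA and SNORD genes formed the other group, and no promoter was checked. In reattached against suspended cells the median was -0.84 (interval -0.95 to -0.18) for the own-promoter group and -0.10 (interval -0.13 to -0.05) for the SNORA and SNORD group. Some small structural RNA genes, such as RNU4-1 and RNU4-2, are near-identical copies whose probes may not tell them apart. The medians and intervals over genes count such copies as separate members. Noise of dim probes would give a median near 0 among bright members, but the 36 members with a mean log2 level of 7 or more had 0.30 (interval 0.16 to 0.40). A uniform gain of all RNA without a poly(A) tail, as a difference in RNA preparation could give, would raise tailless histone mRNAs alike. The 22 clustered histone genes had a median of -0.15 (interval -0.34 to 0.02). Whether the transcripts their probes read lacked a tail was not measured, and histone genes may have been lowered at the same time. The histone values therefore do not decide this. Bright members of the own-promoter group (median 0.61, 11 genes) and of the SNORA and SNORD group (0.27, 24 genes) differed by 0.35 (interval -0.10 to 0.64). Suspension itself, a difference of this single RNA sample, and size-dependent loss of RNA stay open and untested.

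The SPANX genes were lower in suspension, with log2 differences of -2.08 to -1.62, and higher again after reattachment by 1.00 to 1.29. The SD over the 5 genes was 0.17, under the SD of 0.20 between probes of single genes. Probes that read each other's transcripts would give this, and so would shared regulation of neighboring copies, so they cannot be told apart here because the members are near-identical. Counted as 1 gene, they left 68 genes at least 2-fold lower in suspension instead of 72.

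A reattached array between the other 2 could be a mixture of attached and still suspended-type cells. The best single fraction for the 127 genes at 2-fold was 48.9% suspended-type RNA, and simulated unchanged arrays gave 49.8% for genes selected in the same way. Equal noise on each simulated array sets that 49.8% in advance, so it cannot decide the question. The fraction by itself does not show a mixture. Of 42 lists, 7 had a median deviation from the mixing line whose bootstrap interval over genes excluded 0, while simulated mixtures gave 3.24 on average and up to 7. At fractions tried in steps of 5%, 4 lists, the fewest, did so at 0%, which is no suspended-type RNA, and 7 at 25%. From 30% to 50% the number was 8, above the simulated highest. It was 6 at 55%, 9 at 60%, 10 at 65% and 13 to 15 from 70% to 100%. Up to 25% and at 55% the numbers stayed inside the simulated range, so a single fraction cannot be told from other causes here. Chance extremes of single probes on the suspended array would give second probes of either sign, but 87.1% of 31 second probes (27, exact interval 70.2 to 96.4) had the same sign as the first; partial return within each cell, a mixture, and differences between single RNA samples stay open.

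In 9984 genes detected on all 3 arrays, reattached cells lay at least 1.5-fold above both other arrays in 6 (BPTF, LRRC72, SNORD22, TMEM63B, ZNF556 and ZNF600) and below both in 1, RN7SK (-1.26 against suspended and -0.64 against adherent cells).

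The criteria of 2 tests were altered after their values were seen. For the histone test the first criterion asked that the whole interval lie below 0, under which -0.34 to 0.02 was undecided, and the one used asks that it lie below the interval of the small RNA genes. For the single fraction, the first version set the SD of 0.352 around the mixing line against simulated noise, and it was dropped because a spread between single samples cannot be judged against technical noise. The next version took 7 lists against the 2.1 expected from the interval level alone and read this as excluding a single fraction, which the simulated mixtures did not bear out. The histone criterion was later asked of all 7 normalizations, and it held in 7. The comparison of the own-promoter group, set by symbol, with the SNORA and SNORD group was tried besides these. Over all members the groups differed by 0.45 (interval 0.04 to 0.68) in suspended against adherent and by -0.74 (interval -0.87 to -0.08) in reattached against suspended cells, but among members with a mean log2 level of 7 or more the intervals, -0.10 to 0.64 and -0.99 to 0.02, included 0. In reattached against adherent cells the difference was -0.19 (interval -0.33 to 0.003) over all members. Among members with a mean log2 level of 7 or more it was -0.26 (interval -0.42 to -0.02), which excluded 0.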
